A study of Mus musculus with 6 samples.

How the data were processed

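RNA-seq was performed on total RNA from bone marrow cells of the femurs of wild-type mice. The 6 libraries formed 2 groups of 3, control mice and mice kept under hindlimb unloading for 4 weeks, and each library was placed in its group by its title. RNA was extracted with TRNzol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. Base calling with CASAVA, alignment with HISAT2 2.0.5 to mm10 and counting with featureCounts 1.5.0-p3 are named per the submitters' processing notes. The roles are those these tools usually have. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Reads shared by near-identical copies or by overlapping antisense genes therefore could not be assigned with certainty.

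The deposited table held raw read counts per gene for each library, with no normalization, as its whole numbers and differing column totals showed. It also listed a gene length, position and biotype for each gene, which were used as deposited. The table had 54532 genes, of which 27245 had no count in any library. Totals ran from 15850986 to 17775506 counts per library, and 3 counts, the limit used for a gene at 0, corresponded to 0.169 to 0.189 CPM. Such limits cover counting error only, because the reads carried no molecular identifiers.

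Genes were kept by edgeR's filterByExpr with its default settings, which left 15015 genes. Libraries were scaled with TMM factors, and groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels per group are TMM-normalized CPM as mean ± SD over 3 libraries. Standard errors of log2 fold changes were computed as the fold change divided by the square root of its F statistic. Log2 CPM used a prior count of 2.

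Gene lists for 49 marrow cell types, bone cells, pathways and stress programs were fixed before the data were examined, with 966 symbols in all, of which 839 genes were tested. Lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and adjustment over the 49 lists. The same test was run with a correlation estimated for each list, and fry was run as a self-contained test of a shared direction. Counts of members past the threshold are given over all genes and adjusted over the list alone. Genes were named by a rule also fixed beforehand. It took up to 10 protein-coding genes per direction among called genes with separated groups, a mean of at least 1 CPM and no predicted-gene or pseudogene symbol. It also took up to 4 members with the smallest p in the direction of each called list, a preset group of genes of bone turnover and marrow inflammation, and the 5 genes with the smallest p in each direction. The first part named no gene.

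The fits were checked on simulated counts drawn from the means, dispersions and depths of these libraries, with a known fold given to a random set of genes. For this comparison edgeR, run on 14729 genes, recovered 17.9% of the genes changed 1.5-fold, 70.1% of those changed 2-fold and 86.2% of those changed 4-fold. DESeq2 recovered 35.8%, 76.1% and 86.4% on 15015 genes, and 15.9% of its calls were genes simulated without a change, against 8.73% for edgeR. The simulation drew genes independently and with the same dispersion in every library. In the real data the unloaded 1 library deviated more, with an SD of log2 deviations of 0.347 against 0.146 to 0.195 in the others. These rates may therefore not hold for the real libraries.

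Alternatives chosen before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, protein-coding genes alone, removal of the hemoglobin genes and the 20 genes with the most counts, stricter thresholds, each library left out in turn, and the replicate number as a block. A fit with the GC trend of each library removed, limma-voom with library weights, a robust edgeR fit and DESeq2 with the unloaded 1 library left out were added after seeing the data. GC content came from the GENCODE M21 transcripts and was known for 99.9% of tested genes. No pair of libraries agreed within sampling noise, since chi-square per degree of freedom ran from 7.20 to 38.5 over the 15 pairs, so each library counted once.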

Results

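Bone marrow cells freshly taken from the femurs of wild-type mice were profiled by RNA-seq. Hindlimb unloading, in which the hind limbs are lifted off the cage floor so that they bear no weight, was applied for 4 weeks in 3 samples as a model of disuse osteoporosis, and 3 samples came from mice without it. The control libraries held 17775506, 16878388 and 16727836 counts, and the unloaded libraries 15850986, 16543465 and 16357961. Depth compared between the groups gave an exact permutation p of 0.1 (n = 3 per group), the smallest that 3 against 3 allows. Between 21906 and 22371 genes had at least 1 count in a library. The labels do not say whether the replicates of a group came from separate animals, so the p-values measure the spread between these samples.

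Neutrophil genes were the most abundant in both groups, with the granule gene Ngp at 12283 ± 804 CPM in controls and 11233 ± 1431 CPM after unloading (SD, n = 3). Hemoglobin transcripts made up 0.350% ± 0.0529 of counts in controls and 0.498% ± 0.0935 in unloaded samples (SD, n = 3; exact permutation p = 0.2). Ribosomal protein genes took 3.34% ± 0.231 and 3.58% ± 0.238, with an exact permutation p of 0.4. The unloaded 1 library differed from the other 5. It lay at 51.3 on the first principal component of log2 CPM, which carried 34.8% of the variance, while the others lay between -13.7 and -7.37. Mitochondrially encoded transcripts made up 0.439% of its counts and 1.05% to 1.27% in the others. In that library Vcan, Cd14, Fkbp5 and Hdc were high, at 253, 75.8, 275 and 936 CPM against means of 49.1, 24.6, 97.9 and 337 CPM over the other 5, and these genes were chosen after their values were seen.

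**Figure D1:**
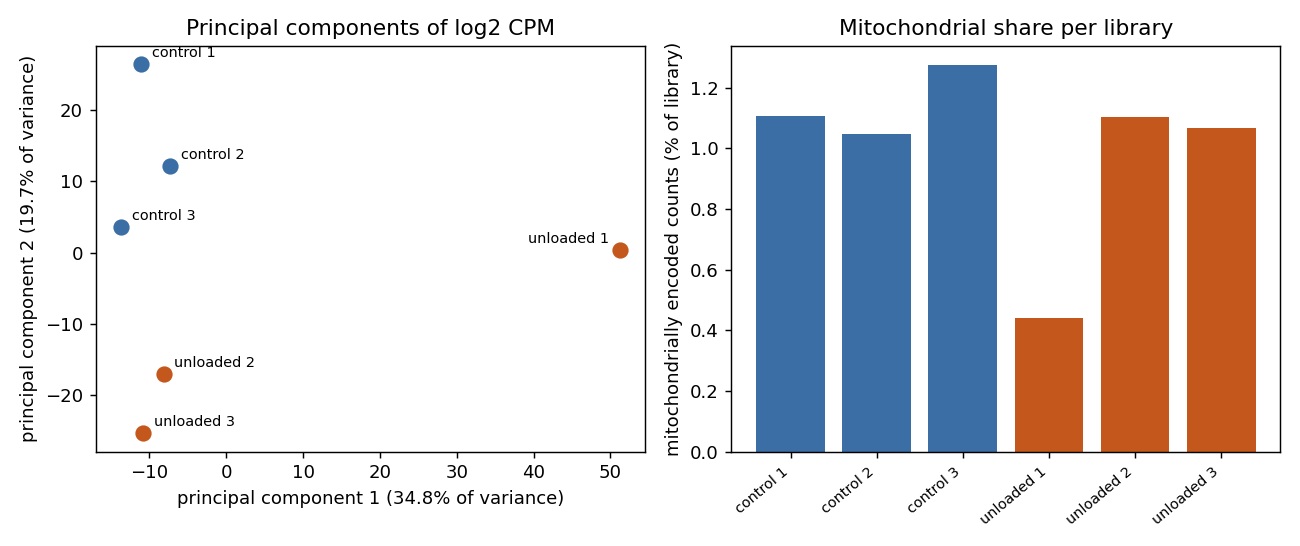
Left, scores of the 6 libraries on the first and second principal components of log2 CPM, with 34.8% and 19.7% of the variance. Right, mitochondrially encoded counts as a percentage of each library, with control libraries in blue and unloaded libraries in orange. Unloaded 1 sits alone at 51.3 on the first component and has 0.439% mitochondrial counts, and the second component places the 3 controls above the other 2 unloaded libraries.

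The comparison of unloaded with control marrow asked which transcripts of marrow and bone cells differ after 4 weeks without weight bearing. By camera with a preset correlation between genes, lists typical of megakaryocytes and platelets, B-cell precursors, dendritic cells, osteoclasts and endothelium were lower in unloaded marrow, and lists of T cell, NK cell and hemoglobin-synthesis genes were higher. None of these lists was called by camera with an estimated correlation (smallest adjusted p = 0.316) or by fry (smallest adjusted p = 0.150). Among single genes, the osteoclast protease gene Ctsk was at 12.2 ± 1.53 CPM in controls and 5.0 ± 1.72 CPM after unloading (SD, n = 3). Stfa1, which encodes a stefin A protease inhibitor of myeloid cells, was at 4.95 ± 1.28 and 15 ± 2.89 CPM. No single gene passed edgeR's quasi-likelihood test over all genes.

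Of 15015 genes tested, 0 were called by edgeR, with a smallest adjusted p of 0.153 for BC100530. At an unadjusted p under 0.05 there were 879 genes, 401 higher and 478 lower, where chance alone gives 751 on average. Other ways of dividing the 6 libraries 3 against 3 gave 353 to 1230 such genes, a range that holds the real 879. Upper-quartile scaling turned the balance of higher and lower genes to 466 and 418. The 3 unloaded values lay beyond all 3 control values for 820 genes above and 961 below, 11.9% of those tested against 10% by chance. DESeq2 called 35 genes, 11 higher and 24 lower, and limma-voom called 0, with 871 at an unadjusted p under 0.05. Without the unloaded 1 library edgeR called 5 genes and DESeq2 64, of which 29 were also among the 35. With any other library left out edgeR called 0. The smallest edgeR adjusted p was then 0.999 without control 1, 0.735 without control 2 and 0.744 without control 3. It was 0.0706 without unloaded 2 and 0.169 without unloaded 3. Without a low-count filter edgeR called 183.

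The genes with the smallest p among the higher ones were BC100530, Stfa1, Ighv1-15, Msr1 and Rpl17. BC100530 (ENSMUSG00000071561, mm10 chromosome 16, 36359382 to 36367748) and Stfa1 (ENSMUSG00000071562, chromosome 16, 36276951 to 36285373) belong to the stefin A gene cluster. BC100530 stood at 3.27 ± 0.372 CPM in controls and 10.7 ± 1.98 CPM after unloading (SD, n = 3), a log2 fold change of 1.70 ± 0.22 (SE). For Stfa1 the log2 fold change was 1.6 ± 0.24, with an edgeR adjusted p of 0.276 and a DESeq2 adjusted p of 1.9e-06. Without unloaded 1 both passed edgeR's test, each at an adjusted p of 0.0301, but neither passed with any other library left out. Copies in this cluster are near-identical, so the split of reads among them is uncertain. The scavenger receptor gene Msr1 was at 12.9 ± 1.34 and 24.0 ± 4.73 CPM (log2 0.90 ± 0.17; edgeR adjusted p = 0.313, DESeq2 adjusted p = 0.0052). Rpl17, a ribosomal protein gene, had a log2 fold change of 0.56 ± 0.11, while its processed pseudogene Rpl17-ps10 had -0.41 ± 0.12, and reads can be exchanged between such copies. The immunoglobulin segment Ighv1-15 was at 1.47 ± 0.629 and 5.06 ± 1.01 CPM.

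The lower genes with the smallest p were Cx3cr1, Gm21378, Ifi27l2a, Fam129c and Fam43a. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), the fractalkine receptor of non-classical monocytes, was at 59.2 ± 1.39 CPM in controls and 37.3 ± 3.24 after unloading (SD, n = 3). Its log2 fold change was -0.67 ± 0.11 (SE), with an edgeR adjusted p of 0.288 and a DESeq2 adjusted p of 0.00157. Fam129c (ENSMUSG00000043243, chromosome 8, 71597648 to 71607936), which is expressed in B cells, went from 92.9 ± 3.04 to 58.3 ± 7.31 CPM. Its edgeR adjusted p was 0.288 with all libraries and 0.0210 without unloaded 1, but it did not pass with any other library left out. Ifi27l2a, an interferon-inducible gene, stood at 29.6 ± 2.68 and 16.4 ± 2.13 CPM (log2 -0.86 ± 0.14; DESeq2 adjusted p = 0.00156). Fam43a had a log2 fold change of -0.75 ± 0.13. The processed pseudogene Gm21378 had -1.51 ± 0.25, at 4.68 and 1.64 CPM, and as a pseudogene it can take reads from a parent gene.

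**Figure D2:**
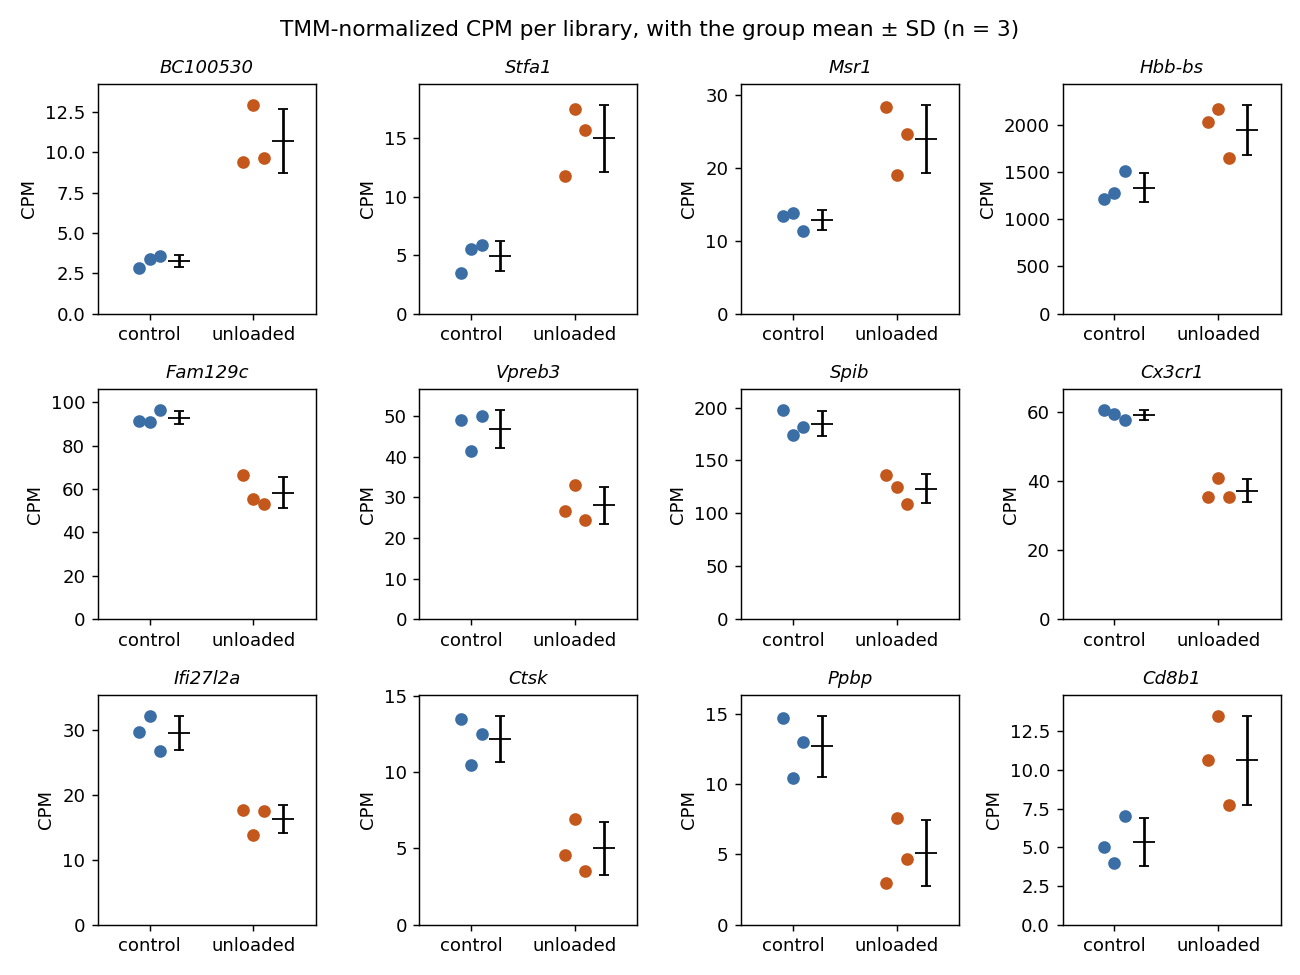
TMM-normalized CPM of 12 named genes in each of the 3 control (blue) and 3 unloaded (orange) libraries, on linear axes that start at 0, with the group mean ± SD beside the points. In each panel the 3 unloaded values lie on one side of the 3 control values, as for Ctsk (12.2 against 5.0 CPM) and Stfa1 (4.95 against 15 CPM).

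By camera with its preset correlation, 17 of the 49 lists were called, 13 lower and 4 higher. Other ways of dividing the 6 libraries 3 against 3 gave 10 to 19 called lists. With an estimated correlation 0 were called, the smallest adjusted p being 0.316, and 7 lists were at an unadjusted p under 0.05. Fry called 0 with a smallest adjusted p of 0.150, again with 7 at an unadjusted p under 0.05. No member of any list passed over all genes by edgeR, so the counts of members below are adjusted over the list alone. For 11 of the 17 lists the mean log2 CPM of all 3 unloaded libraries lay beyond that of all 3 controls. The lists were called from these same libraries, so this separation is not separate evidence.

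In the list of platelet and megakaryocyte genes 16 of 17 members had a negative fold change, with a median of -0.51, or -0.33 without unloaded 1, and 4 passed when adjusted over the list alone. The camera adjusted p was 2.0e-09, and the adjusted p was 0.316 with an estimated correlation. Ppbp, a platelet chemokine gene, was at 12.7 ± 2.17 CPM in controls and 5.10 ± 2.33 after unloading (SD, n = 3), a log2 fold change of -1.32 ± 0.30. The platelet receptor gene Treml1 had -1.07 ± 0.27 and the chemokine gene Pf4 -0.73 ± 0.23. Other lineage genes moved little, with Itga2b at -0.05 ± 0.12 and Gp1ba at 0.07 ± 0.27, although both were at -0.15 without unloaded 1.

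In the list of pro-B and pre-B cells 17 of 20 members had a negative fold change, with a median of -0.23, and 4 passed when adjusted over the list alone. Camera gave an adjusted p of 9.2e-09, against an adjusted p of 0.385 with an estimated correlation. Vpreb3, a gene associated with the pre-B receptor, was at 46.8 ± 4.72 CPM in controls and 28 ± 4.52 after unloading (SD, n = 3; log2 -0.74 ± 0.14). The recombinase gene Rag1 (-0.66 ± 0.19) and the transcription factor genes Bach2 (-0.69 ± 0.13) and Sox4 (-0.64 ± 0.18) were the other 3. The early enzyme gene Dntt, at 0.06 ± 0.15, was not lower. The mature B cell list was not called (median 0.04; camera adjusted p = 0.754), but without unloaded 1 it was, as lower (camera adjusted p = 0.00643).

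Both dendritic cell lists were called as lower by camera with its preset correlation. Plasmacytoid markers had a median of -0.24 with 12 of 13 members negative (camera adjusted p = 4.4e-05; adjusted p = 0.316 with an estimated correlation). Spib, a transcription factor gene of these cells that B cells also express, was at 185 ± 11.9 CPM in controls and 123 ± 13.6 after unloading (SD, n = 3), and was the 1 member that passed when adjusted over the list alone. Conventional dendritic markers had a median of -0.17 with 7 of 12 negative, led by Irf4 (-0.52 ± 0.15) and Cd209a (-0.64 ± 0.19), the 2 members that passed over the list alone. Irf4 is also in the plasma cell list, so it is not specific to dendritic cells. The camera adjusted p was 0.0126, and the adjusted p was 0.316 with an estimated correlation. This call ended without unloaded 2 (camera adjusted p = 0.0723) and without unloaded 3 (0.0734; median -0.08), and the median was -0.11 without control 2 and -0.09 without control 3.

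Interferon-response genes had negative fold changes in 25 of 30 members, with a median of -0.17, or -0.26 without unloaded 3 (camera adjusted p = 7.4e-06; adjusted p = 0.385 with an estimated correlation). The median was -0.14 without control 3 (camera adjusted p = 0.0024) and -0.14 without unloaded 2 (camera adjusted p = 0.0152). Ifi27l2a and Ifit3 (-0.88 ± 0.22) passed when adjusted over the list alone. Immediate early genes, which are induced within minutes by stimulation or handling, had negative fold changes in 18 of 21 members, with a median of -0.39 that was -0.14 without control 1. Camera gave an adjusted p of 1.3e-08, and the adjusted p was 0.432 with an estimated correlation. Dusp2 (-0.53 ± 0.13) passed over the list alone. Junb was at 1112 ± 160 CPM in controls and 782 ± 176 CPM after unloading (SD, n = 3), a log2 fold change of -0.51 ± 0.17, or -0.33 without unloaded 1. In the list of inflammatory cytokines and NF-kB targets 16 of 24 members had negative fold changes, with a median of -0.22, or -0.12 without unloaded 2, and 0 past the threshold over the list alone. Nlrp3 was at -0.31 ± 0.11 and Tnf at -0.48 ± 0.18, or -0.28 without unloaded 1. Its camera adjusted p was 0.00823, 0.127 without control 1, and the adjusted p was 0.316 with an estimated correlation.

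The lists of T cell and NK cell genes were called as higher by camera with its preset correlation. Of 18 T cell genes 16 were positive with a median of 0.35, led by Cd8b1 at 5.35 ± 1.56 CPM in controls and 10.6 ± 2.89 after unloading (SD, n = 3), and 0 passed over the list alone. Cd4, which monocytes and dendritic cells can also express, was among the 2 lower members, at -0.48 ± 0.20. The median was 0.54 without control 3, 0.55 without unloaded 3 and 0.14 without unloaded 2. Camera gave an adjusted p of 5.5e-05, 0.175 without unloaded 2, and the adjusted p was 0.688 with an estimated correlation. NK genes had a median of 0.28 with 14 of 16 positive, led by the granzyme gene Gzma (0.98 ± 0.26) and the receptor gene Klra4 (0.84 ± 0.29), with 0 past the threshold over the list alone. The camera adjusted p was 0.000251, and the adjusted p was 0.385 with an estimated correlation. Members of the Klra family are close paralogs, so their separate counts are uncertain.

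All 14 genes of globin and heme synthesis had a positive fold change, with a median of 0.16, or 0.28 without unloaded 1 (camera adjusted p = 5.5e-05; adjusted p = 0.585 with an estimated correlation). Hbb-bs was at 1332 ± 154 CPM in controls and 1945 ± 267 after unloading (SD, n = 3). Hba-a1 was at 1816 ± 219 and 2516 ± 392 CPM, and both passed when adjusted over the list alone. Adult globin copies are near-identical in pairs, so the single-gene values are uncertain. Fold changes of members such as Fech (0.05 ± 0.19) and Cpox (0.08 ± 0.17) were within their errors, and without unloaded 1 they were 0.26 and 0.28. Without unloaded 2 the call ended (median 0.055, camera adjusted p = 0.112). Erythroid precursor genes were not called (median 0.08, camera adjusted p = 0.179), although without unloaded 1 they were, as higher (camera adjusted p = 7.5e-10).

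**Figure D3:**
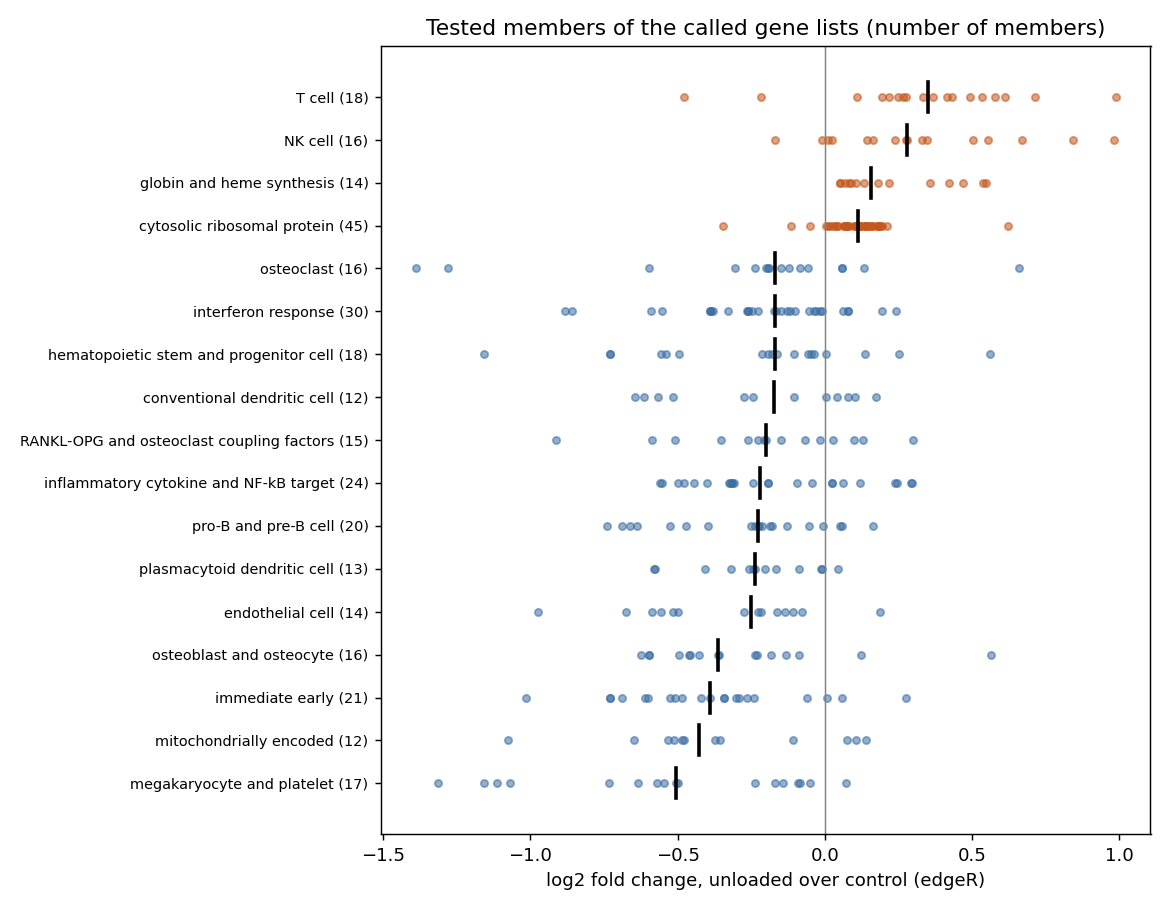
Log2 fold changes, unloaded over control, of each tested member (points) of the 17 called lists, with the list median as a black bar and the number of members in brackets. Lists called lower are blue and lists called higher are orange. The megakaryocyte and platelet list has a median of -0.51 and the T cell list one of 0.35.

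The osteoclast list had negative fold changes in 12 of 16 members, with a median of -0.17 (camera adjusted p = 0.00129; adjusted p = 0.316 with an estimated correlation). Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), which encodes cathepsin K, the main collagen-degrading protease of osteoclasts, had a log2 fold change of -1.28 ± 0.25. Its edgeR adjusted p was 0.313 and its DESeq2 adjusted p 0.00251, and it was the 1 member that passed over the list alone. The proton pump subunit gene Atp6v0d2 had -1.39 ± 0.48, from 1.66 ± 0.216 to 0.627 ± 0.378 CPM. Mmp9, which the mature neutrophil list also holds, had -0.31 ± 0.12, or -0.19 without unloaded 1, at 3104 ± 120 CPM in controls. The osteoclast list also shares Car2 with the erythroid precursor list and Itgb3 with the megakaryocyte list, so it is not specific to osteoclasts. Acp5, the gene of tartrate-resistant acid phosphatase, had 0.06 ± 0.18, and Nfatc1, the transcription factor gene of osteoclast formation, -0.19 ± 0.11.

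RANKL-OPG and osteoclast coupling factors had negative fold changes in 11 of 15 members, with a median of -0.20, or -0.12 without control 2 or without unloaded 3 (camera adjusted p = 0.00282; adjusted p = 0.316 with an estimated correlation). Pdgfb (-0.91 ± 0.25) and Sema4d (-0.51 ± 0.14) passed when adjusted over the list alone, and Csf1, the macrophage growth factor gene, had -0.26 ± 0.14. Tnfsf11 and Tnfrsf11b, which encode RANKL and its decoy receptor, were too low to test. Tnfsf11 had 2 to 18 counts per library and Tnfrsf11b had 0 in each, which allows up to 0.189 CPM in the shallowest library.

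Osteoblast and osteocyte genes had negative fold changes in 14 of 16 members, with a median of -0.36 and 0 past the threshold over the list alone (camera adjusted p = 0.0453; adjusted p = 0.808 with an estimated correlation). Col1a1 was at 77.1 ± 43.8 CPM in controls and 51.0 ± 26.4 after unloading (SD, n = 3), overlapping between groups. Leaving out unloaded 1, unloaded 2, control 1 or control 3 ended this call, with camera adjusted p of 0.340, 0.0723, 0.121 and 0.585. The median was -0.21 without unloaded 1 and -0.04 without control 3. Alpl (-0.23 ± 0.29), Bglap (-0.46 ± 0.61), Spp1 (-0.18 ± 0.16) and Runx2 (-0.09 ± 0.14) overlapped between the groups, and Bglap has close paralogs that make its count uncertain. Sost, Dmp1 and Sp7 were not testable, with Sost at 0 counts in all libraries.

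Endothelial genes had negative fold changes in 13 of 14 members, with a median of -0.25, or -0.46 without unloaded 1, and 0 past the threshold over the list alone (camera adjusted p = 0.00131; adjusted p = 0.316 with an estimated correlation). The list stayed called with each library left out, but its camera adjusted p was 0.0229 without unloaded 1 and 0.0447 without unloaded 3 (median -0.21). It was 0.0293 without control 1 and 0.0341 without control 3. Tie1 had -0.68 ± 0.25 and Vwf, which the megakaryocyte list also holds, -0.50 ± 0.19. Marrow stromal genes were not called (median -0.12, or -0.07 without unloaded 1, camera adjusted p = 0.754), with Cxcl12 at 35.6 ± 12.8 and 38.0 ± 3.27 CPM. Adipocyte genes were not called either (median 0.06, or -0.06 without unloaded 1, camera adjusted p = 0.802), with Adipoq at 0.41 ± 0.51 and Pparg at -0.31 ± 0.32. The cytokine genes Il1b (-0.19 ± 0.17, or -0.04 without unloaded 1) and Il6 (0.12 ± 0.72) overlapped between groups, and Il7 had 2 to 8 counts per library.

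**Figure D4:**
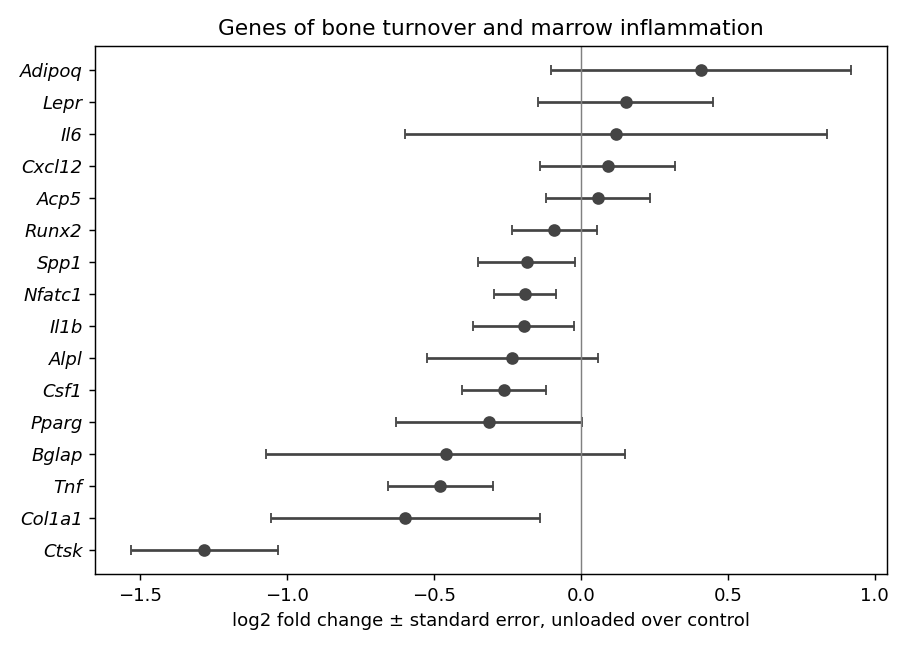
Log2 fold changes, unloaded over control, of 16 tested genes of bone turnover and marrow inflammation, with standard errors from the edgeR fit (3 libraries per group). Ctsk, at -1.28 ± 0.25, lies farthest from 0, and DESeq2 called it over all genes (adjusted p = 0.00251) while edgeR called none of the 16.

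The calls of 3 further lists ended without the unloaded 1 library. Mitochondrially encoded genes were lower, with a median of -0.43 (camera adjusted p = 0.00282; adjusted p = 0.808 with an estimated correlation), but the camera adjusted p was 0.462 without unloaded 1 (median -0.08) and 0.211 without control 3. Ribosomal protein genes had positive fold changes in 42 of 45 members, with a median of 0.11 (camera adjusted p = 0.000615; adjusted p = 0.901 with an estimated correlation), and the camera adjusted p was 0.174 without unloaded 1 (median 0.03) and 0.127 without control 1 (median 0.06). Stem and progenitor genes had negative fold changes in 14 of 18 members, with a median of -0.17. The camera adjusted p was 0.00823, 0.217 without unloaded 1 (median -0.06), and the adjusted p was 0.385 with an estimated correlation.

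Lists of neutrophil, cell-cycle and oxidative phosphorylation genes were not called with all 6 libraries. Mature neutrophil genes had a median of -0.06, those of secondary granules -0.01 and those of primary granules -0.11, or -0.07, -0.02 and -0.02 without unloaded 1, with camera adjusted p of 0.754, 0.801 and 0.127. Ngp was at -0.13 ± 0.12 and S100a8 at -0.07 ± 0.13, or 0.015 without unloaded 1. S phase and G2 and M phase genes both had a median of -0.01, each with a camera adjusted p of 0.754, and Mki67 was at 0.11 ± 0.11. Without unloaded 1 the S phase list was called as higher (camera adjusted p = 0.0491, median 0.05), and the G2 and M phase median turned to 0.04 without a call (camera adjusted p = 0.0909). The glucocorticoid response, resident macrophage and MHC class I lists were then called as lower (camera adjusted p = 0.0153, 0.00557 and 0.00557), against 0.255, 0.754 and 0.489 with all libraries. Oxidative phosphorylation genes encoded in the nucleus had a median of 0.02, or 0.03 without unloaded 1 (camera adjusted p = 0.732).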

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

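Counts of genes depended on the tool and the libraries, and list calls depended on how the correlation between genes was set. DESeq2 called 35 genes (11 higher, 24 lower), edgeR without a low-count filter 183 (89 higher, 94 lower), and leaving out 1 library gave 0 to 5 (0 to 3 higher, 0 to 2 lower). Without the filter edgeR's fit drew all gene variances to the trend, where the filtered fit had 6.69 prior degrees of freedom. Of the alternatives chosen after seeing the data, limma-voom with library weights called 8 (3 higher, 5 lower) and DESeq2 without unloaded 1 called 64 (16 higher, 48 lower), while a robust edgeR fit and removal of GC trends called 0. The replicate number as a block called 1 gene, Stfa1 (1 higher). Deviations of control and unloaded libraries with the same number correlated at 0.031, -0.063 and 0.019, so the numbers gave no sign of pairing, and the block changed no other call of a gene but added cholesterol synthesis to the lists called, as lower (camera adjusted p = 0.0485). Camera called 17 lists, 14 to 21 in the other settings, and 0 with an estimated correlation or with fry. Of the 17, 9 lost their call only with an estimated correlation and with fry, and 8 also lost it with some single library left out. The osteoblast and osteocyte list lost its call in 12 of 21 settings. Among them were DESeq2, limma-voom, no low-count filter and protein-coding genes alone. Of the 88 genes named by the rule set beforehand, 7 turned sign, and for each the cause was not tested. Leaving out 1 library gave -0.18 to 0.060 for Runx2 (0.021 with library weights, 0.055 with DESeq2 without unloaded 1), -1.24 to 0.15 for Bglap, and -0.39 to 0.024 for Alpl. It gave -0.10 to 0.22 for Acp5 (-0.033 with library weights, -0.11 with DESeq2 without unloaded 1), -0.18 to 0.26 for Cxcl12, and -0.48 to 0.033 for Pparg. For Il6 it gave -0.38 to 0.65, with -0.42 from limma-voom and -0.066 with the block. Another scaling shifted the median log2 fold change from 0.0054 to at most 0.0241 and called no gene, but upper-quartile scaling turned the balance at an unadjusted p under 0.05 from 401 higher and 478 lower to 466 and 418.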

Other observations

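The tests weighed below were chosen after the results were seen, as were the genes named here beyond Cx3cr1. Monocyte genes went both ways. Cx3cr1 (log2 -0.67 ± 0.11 SE) and Ace, from 24.2 ± 3.92 to 15.4 ± 1.82 CPM (SD, n = 3), are markers of non-classical monocytes, and both were lower in all 3 unloaded libraries. F13a1 (0.37 ± 0.15, or 0.19 without unloaded 1) and Ccr2 (0.36 ± 0.15), typical of classical monocytes, had higher means with overlap, while Ly6c2, another of their markers, had a lower mean (-0.22 ± 0.15, or -0.07 without unloaded 1) and Fn1 (0.01 ± 0.16) and Lyz2 (-0.08 ± 0.12) differed by less than their errors. Vcan was at 25.5 ± 10 and 141 ± 105 CPM, higher in all 3 unloaded libraries, with a log2 fold change of 2.46 ± 0.51, or 1.73 without unloaded 1. The monocyte list was not called (median -0.14; camera adjusted p = 0.116) but was called as lower without unloaded 1 (camera adjusted p = 0.00643), and 3 members, Vcan among them, passed edgeR adjusted over the list alone.

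Among clock genes, Arntl (-0.54 ± 0.15) was lower in all 3 unloaded libraries, while Nr1d1 (0.79 ± 0.30), Ciart (0.69 ± 0.34) and Cry2 (0.31 ± 0.14) were higher in all 3. Dbp (0.06 ± 0.20, or -0.04 without unloaded 1) and Per1 (-0.41 ± 0.29, or -0.68 without unloaded 1) overlapped. The list was not called (camera adjusted p = 0.754), and 0 members passed edgeR adjusted over the list alone. Plasma cell genes were mixed. Ighg1 had a log2 fold change of 1.1 ± 0.32, or 0.52 without unloaded 1, and Sdc1 of -0.61 ± 0.21. By edgeR 0 members passed adjusted over the list alone (0.0506 for Ighg1 and 0.0726 for Sdc1), and neither gene was called by DESeq2 (adjusted p = 0.865 and 0.512), with the list at a camera adjusted p of 0.754.

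The 6 libraries can be divided 3 against 3 in 10 ways. The real count of genes called by edgeR was 0, which 10 of the 10 splits must reach, so it tests nothing, and the highest other was 4. For DESeq2 it was 1 split, the real one, with 35 genes against a highest other of 18. For lists 2 splits gave 17 or more, and the splits other than the real one called 10 to 19 lists. A camera p as small as the real one arose in no other split for the megakaryocyte, pro-B, NK cell and interferon lists. The same held for both dendritic cell lists and the osteoclast, endothelial and RANKL-OPG lists. All of these were called for a small p in the real split, so its first rank is partly built in and is not separate evidence. For the T cell list and the globin and heme list 3 of the 10 splits reached it, and for the mitochondrially encoded list 6. These splits are too few for a share under 0.05.

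Unloaded 1 stood apart from the other 5 libraries. A GC trend in that library could explain part of it, since the trend carried 20.8% of the variance of its log2 deviations, but with it removed their SD was 0.309, against at most 0.184 in the others. Removing a gene length trend left 0.344. A stronger response to unloading would make its deviations covary more with those of the other 2 unloaded libraries, each taken from a different control. The mean covariance was at most 0.00021, against 0.0086 between unloaded 2 and unloaded 3, but the ranges over 6 pairs of controls overlapped, so this stays open, as may a difference in handling or sampling, which was not tested.

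All 6 tested stefin A genes, on chromosome 16 from 36156811 to 36455392, had higher values in all 3 unloaded libraries than in any control, but they were grouped after BC100530 and Stfa1 were seen and no test of the set was run. The edgeR adjusted p over all genes ran from 0.153 to 0.722, and DESeq2 called 3 of the 6, with adjusted p of 0.166 to 0.337 for Stfa2l1, Stfa3 and Stfa2. Reads shared between paralogs could have come from copies below the filter. The sum over all 29 genes annotated in the cluster was 65.5 ± 16.4 CPM in controls and 126 ± 18.5 after unloading (SD, n = 3), a ratio of 1.92. Exchange of counted reads within the cluster would leave this sum unchanged. Shared reads that were not counted would be missing from it, and their treatment is not given. The sum therefore argues only against exchange of counted reads. A larger share of mature neutrophils would raise their other markers, but the median over 15 of these was -0.059. A sequence difference at the locus between the mice, or exchange with genes elsewhere, may also produce this, and neither was tested.

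Lists of B precursors and megakaryocytes were lower by camera with a preset correlation, but not with an estimated correlation (camera adjusted p = 0.385 and 0.316) or by fry (adjusted p = 0.342 and 0.150). The share of hemoglobin and other abundant transcripts was 10.3% ± 0.275 in controls and 10.1% ± 0.537 after unloading (SD, n = 3). This gives a log2 shift of other genes no lower than -0.010 for any pair of libraries, against list medians of -0.23 and -0.51. Such a shift would move all other genes alike, and TMM scaling and camera's comparison with other genes largely remove it. It was therefore no likely source of these calls from the start, and the share adds little as a test. A lower share of all B precursors would lower lineage-restricted markers equally. The weighted mean of 7 such markers was -0.35 ± 0.071 (SE), or -0.25 ± 0.063 without unloaded 1, and with all libraries they ranged from -0.74 to 0.16. The simulated p for unequal changes was 0.0193, and 0.00485 without unloaded 1. Both the SE and the simulation took the genes' errors as independent, while the correlation estimated for the whole list was 0.357. The test therefore does not exclude a lower share. For 9 restricted megakaryocyte markers the range was -1.32 to 0.07 and the simulated p 0.0490, but without unloaded 1 it was -1.09 to 0.0084 with a simulated p of 0.0789, so a lower share of megakaryocytes and platelets stays open. For B precursors, a lower share of all of them, fewer cells of some stages or lower expression per cell may remain. Bulk counts do not separate these.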
